A study of Danio rerio with 24 samples.

How the data were processed

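Poly(A) RNA of sorted zebrafish cells was measured in 24 libraries, 12 groups of 2. RNA was isolated with RNeasy Mini columns and libraries were made with NEBNext Ultra reagents, per the labels' protocols. The deposited values are FPKM per gene, made by the authors. The submitters' processing notes name FastQC, HISAT, HTSeq, DESeq2 and the genome build GRCz10, without versions or roles. How the gene table was filtered is not given in the sources used here. It holds 25067 genes, 557 of them at 0 in every library.

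FPKM depends on gene length and library total. Read numbers were recovered from it because each gene's values are whole multiples of what 1 read is worth: all 23718 of 23718 genes above 0 in at least 3 libraries gave whole reads within 0.01 reads. On simulated data 99.66% of 23485 genes came back with the simulated reads. An exact 0 is called listed at 0. Reads of near-identical genes may have been split by the counting, and coordinates were not used here.

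Genes with at least 1 FPKM in at least 2 libraries were kept (21024). limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) was fitted to log2(FPKM + 1) over all libraries with 12 group means and no covariates, leaving 12 residual degrees of freedom and a median prior of 5.89. The pseudocount understates changes of genes with low values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and a log2 fold change of at least 1 in size. Adjusted p-values of genes are from limma, for changes in either direction. The 14 comparisons covered cell types over shared stages, successive stages within a cell type, the kidney, and differences of change. In each, the group named first is higher where the value is positive.

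Gene lists of cell type markers and pathways were fixed before the data were examined, as were the comparisons, the naming rule and the alternatives not described as chosen later. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 518 tests. The ribosomal list, filled by name pattern, includes rps6kal, a kinase gene that was called in no comparison. It called 269, 139 up and 130 down, of which 5 held with an estimated correlation. These were embryonic and larval globin in HSPC against EC, HSPC 4 against 3 dpf, kidney HSPC against 4 dpf and DN 52 against 36 hpf, and dissociation stress genes in DN 4 against 3 dpf. Named genes were the 5 called genes with the largest change per direction that had a gene symbol, a mean of at least 5 FPKM in the higher group and no overlap between libraries (not asked of differences of change). Up to 4 members per list were added, called members with the largest change or else those with the highest mean. Of 992 such entries 352 were eligible for description, those of lists a comparison is about and of its 5 called lists with the smallest p. That restriction was set after the list results were seen.

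Alternatives were another pseudocount, no filter, a common FPKM sum, median-of-ratios scaling, the replicate number as a block, arrayWeights, fits of only the groups compared and leaving out each replicate. limma-voom on recovered reads, fits without both low-complexity 4 dpf libraries and each stage alone were chosen after seeing the data. Median-of-ratios scaling and voom were first run in another form, whose calls were seen before the usual definition replaced both. Simulated data, not shown to vary like these libraries, had changes of 2, 4 and 8 times. The fit recovered 56.72%, 100% and 100% in HSPC against EC (18938 genes). It recovered 8.955%, 65.67% and 95.45% in HSPC 3 dpf against 36 hpf (18925) and 0%, 26.87% and 65.15% in the difference EC minus DN (18942). It called 1 to 4 unchanged genes. Recovery and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.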

Results

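Poly(A) RNA was sequenced from cells sorted out of zebrafish carrying a kdrl:mCherry reporter, which marks endothelium, and a CD41:GFP reporter, which marks hematopoietic stem and progenitor cells (HSPCs) and thrombocytes. The tail holds the caudal hematopoietic tissue, where HSPCs expand in the embryo. The 24 libraries formed 12 groups of 2: endothelial cells (EC), HSPCs and double-negative cells (DN) from tails at 36 hours post fertilization (hpf), 3 days post fertilization (dpf) and 4 dpf, DN cells at 52 hpf, and HSPCs and DN cells from kidney marrow at 3 months post fertilization (mpf). HSPC and EC sorts at 52 hpf were not analysed here. The series design names tails at 36 hpf too, but sample titles name the caudal hematopoietic tissue only from 52 hpf on, so comparisons with 36 hpf may include a difference of dissection. The labels do not state separate clutches or sorts, so p-values measure only the spread between these samples, which may be technical. Log2 fold changes are on the log2(FPKM + 1) scale and stand with ± their standard error from limma. FPKM values are given per library, n = 2 per group, replicate 1 first. Values by limma-voom on recovered reads, for each stage alone and without both low-complexity 4 dpf libraries (EC and HSPC replicate 2) come from alternatives chosen after seeing the data.

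The genes behind the reporters were read in every library. kdrl, the endothelial VEGF receptor, was at 5.16 and 3.68 FPKM in libraries labelled EC at 36 hpf, 0.333 and 0.323 at 3 dpf and 0.163 and 0 at 4 dpf. In libraries labelled HSPC it was at 0.963 and 0.988 FPKM at 36 hpf and listed at 0 in all 4 libraries at 3 and 4 dpf. The DN libraries before 3 mpf held 0.562 and 0.283 FPKM at 36 hpf, 0.584 and 0.509 at 52 hpf, 0.257 and 0.387 at 3 dpf and 0.772 and 0.478 at 4 dpf. In the kidney kdrl was at 0.574 and 4.23 FPKM in HSPC and 0 and 6.98 in DN libraries. itga2b, which encodes CD41, was listed at 0 in both EC libraries at 36 hpf and was at 0.428 and 0 FPKM in HSPC libraries of that stage. At 3 dpf it was at 6.55 and 5.72 FPKM in libraries labelled EC and 6.54 and 7.98 in libraries labelled HSPC. At 4 dpf the values were 2.98 and 0 FPKM (EC) and 4.97 and 0 (HSPC), and in the kidney 14.9 and 39.7 (HSPC) and 0.583 and 2.46 (DN). The highest itga2b value in a DN library before 3 mpf was 0.0708 FPKM. At 3 and 4 dpf the libraries labelled EC thus held kdrl within or below the range of those DN libraries, and at 3 dpf itga2b close to the HSPC values, against what their label implies. They are called libraries labelled EC for this reason. The HSPC libraries at 36 hpf and replicate 2 at 4 dpf likewise held little or no itga2b, and each direction drawn from these libraries carries this limit.

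**Figure D1:**
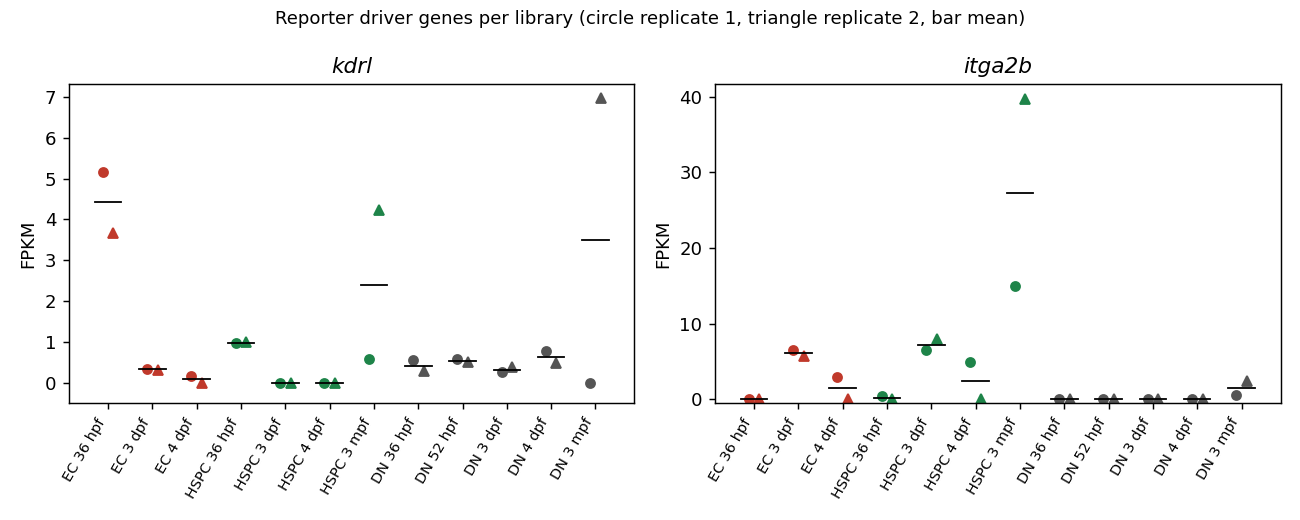
FPKM of kdrl (left) and itga2b (right) in each of the 24 libraries by group, with circles for replicate 1, triangles for replicate 2 and bars for the group mean. kdrl was at 5.16 and 3.68 FPKM in the libraries labelled EC at 36 hpf and 0.333 and 0.323 at 3 dpf, while itga2b was listed at 0 in both at 36 hpf and was at 6.55 and 5.72 FPKM at 3 dpf.

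The recovered reads per library ranged from 1741361 (EC 4 dpf replicate 2) to 21339311 (kidney HSPC replicate 1). EC 4 dpf replicate 2 had 2483 genes above 0, against 19015 in replicate 1. HSPC 4 dpf replicate 2 had 11265 genes above 0, with 43.85% of its FPKM on mitochondrial genes, against 17866 genes and 6.11% in replicate 1. That share was 25.16% and 25.38% in HSPC, 11.14% and 10.19% in EC and 7.49% and 8.05% in DN libraries at 36 hpf, and 13.97% and 13.15% in HSPC at 3 dpf. Spearman correlation across genes, which are not independent replicates, was 0.383 between the EC 4 dpf replicates, 0.740 at HSPC 4 dpf, 0.791 for kidney DN and 0.872 to 0.974 in the other 9 groups. No gene above 0 had equal values in a pair of replicates, and the pairs differed by more than sampling noise (chi-square per gene 10.9 to 349).

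**Figure D2:**
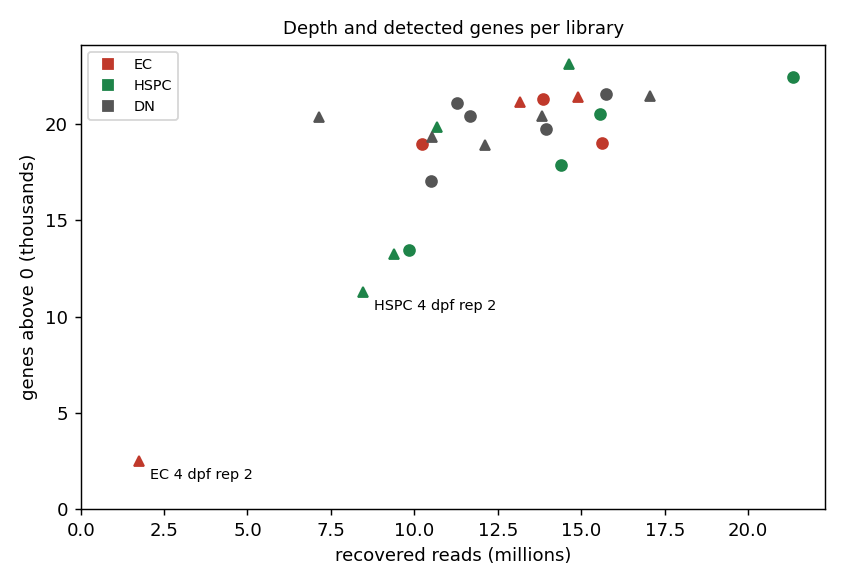
Genes above 0 FPKM (vertical axis) against recovered reads (horizontal axis), with 1 point per library. EC 4 dpf replicate 2 stands apart with 2483 genes at 1741361 reads.

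Marker lists of the sorted and of other cell types were read as mean log2(FPKM + 1) per library. The endothelial list was at 3.26 and 2.82 in EC at 36 hpf, 1.62 and 1.42 in HSPC and 1.27 and 1.45 in DN libraries, and at 1.67 and 1.68, 1.25 and 1.21 and 0.91 and 0.95 at 3 dpf. Neutrophil genes stood at 7.31 and 7.02 in libraries labelled EC at 3 dpf, above HSPC (4.96 and 4.82) and DN (2.71 and 3.19). The HSPC regulator list was at 4.46 and 4.38 in EC and 4.46 and 4.36 in HSPC libraries of that stage, and at 2.29 and 2.18 in DN. Epidermal genes were at 7.24 and 7.23 in HSPC libraries at 36 hpf, against 6.26 and 6.61 in EC and 6.04 and 6.22 in DN, and at 1.77 and 1.75 in HSPC at 3 dpf. Skeletal muscle genes were at 5.57 and 5.65 in HSPC at 36 hpf and 0.45 and 0.52 at 3 dpf, so HSPC libraries at 36 hpf carried epidermal and muscle transcripts above those of the DN sort (4.33 and 4.83).

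**Figure D3:**
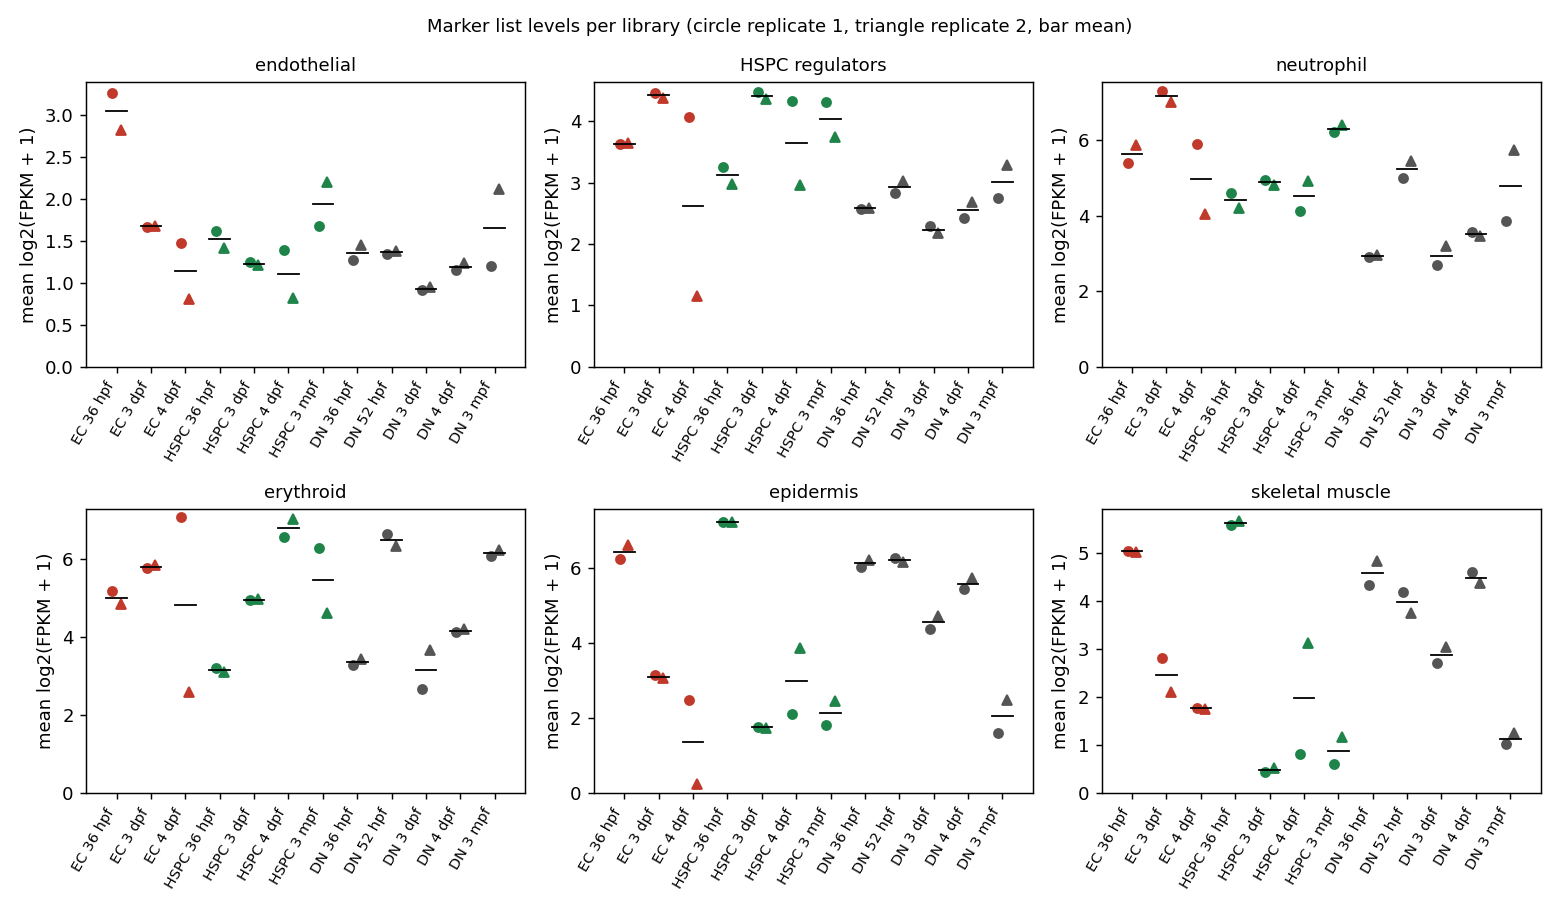
Mean log2(FPKM + 1) of 6 marker lists in each library, by group, with circles for replicate 1, triangles for replicate 2 and bars for the group mean. The neutrophil list was at 7.31 and 7.02 in the libraries labelled EC at 3 dpf and the epidermal list at 7.24 and 7.23 in the HSPC libraries at 36 hpf.

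HSPC libraries were compared with EC libraries over 36 hpf, 3 dpf and 4 dpf, by their labels. The larval globin genes hbbe1.3 (-5.62 ± 0.59), hbae3 (-3.69 ± 0.29) and hbbe1.1 (-3.50 ± 0.34) were lower in HSPC libraries, as was alas2, the first enzyme of erythroid heme synthesis (-3.46 ± 0.44), with the collagenase mmp13a at -3.69 ± 0.57. Reads of near-identical globin copies can be split between them, so single globin genes are uncertain. The 5 genes with the largest increase were stc1l, a stanniocalcin (5.71 ± 1.29), the hormone fgf23 (3.63 ± 0.67, listed at 0 in both EC 4 dpf libraries), the prohormone convertase pcsk2 (3.35 ± 0.70), the EGF receptor ligand areg (3.01 ± 0.45) and cdh16 (2.98 ± 0.42). Their adjusted p lay between 0.00105 and 0.0408. Among 26 endothelial genes 4 were lower and 22 did not pass (4 adjusted over the list alone, camera adjusted p = 3.2e-11, adjusted p = 0.191 with estimated correlation). Examples were the water channel gene aqp1a.1 at -2.62 ± 0.41 and the tight junction gene cldn5b at -1.43 ± 0.32. Of 27 HSPC regulator genes, 1 was lower and 26 did not pass (1 adjusted over the list alone, camera adjusted p = 0.463). This was spi1b, a myeloid transcription factor (-2.35 ± 0.52). By limma 0 of 14 thrombocyte genes passed (3 at an unadjusted p under 0.05, 0 by voom, 2 adjusted over the list alone, camera adjusted p = 0.962). An example was nfe2 at 0.93 ± 0.59. Of 9 embryonic and larval globin genes, 5 were lower and 4 did not pass (8 adjusted over the list alone, camera adjusted p = 7.8e-20, adjusted p = 0.0223 with estimated correlation). Among 17 neutrophil genes 5 were lower and 12 did not pass (7 adjusted over the list alone, camera adjusted p = 3.7e-09, adjusted p = 0.191 with estimated correlation). Examples were mmp9 at -3.35 ± 0.46 and lyz, lysozyme, at -1.88 ± 0.42. Of 18 notochord and cartilage genes, 6 were lower and 12 did not pass (8 adjusted over the list alone, camera adjusted p = 2.0e-11, adjusted p = 0.183 with estimated correlation). Members included col2a1a, a cartilage collagen, at -3.29 ± 0.59 and col9a2 at -2.55 ± 0.49. Among 32 neural genes 1 was lower and 31 did not pass (10 adjusted over the list alone, camera adjusted p = 8.8e-13, adjusted p = 0.261 with estimated correlation). This was fabp7a (-1.59 ± 0.36, listed at 0 in both HSPC 3 dpf libraries). In all limma called 167 of 21024 genes, 48 higher and 119 lower (70 and 81 with median-of-ratios scaling). At 36 hpf alone 156 higher and 130 lower were called, at 3 dpf alone 18 higher and 164 lower and at 4 dpf alone 14 higher and 2 lower. Higher and lower genes numbered 18 and 49 with a pseudocount of 0.1, 0 and 5 with arrayWeights, 24 and 42 with only the groups compared, 47 and 825 by limma-voom, 108 and 522 without both low-complexity libraries, 3895 and 857 without EC 4 dpf replicate 1, 177 and 159 without HSPC 4 dpf replicate 1, and 63 and 69 without HSPC 4 dpf replicate 2. The total was 77 or 89 without EC 36 hpf replicate 1 or 2, 91 or 71 without HSPC 36 hpf replicate 1 or 2, 80 or 102 without EC 3 dpf replicate 1 or 2, 90 or 107 without HSPC 3 dpf replicate 1 or 2, and 545 without EC 4 dpf replicate 2. Libraries labelled EC at 3 and 4 dpf held little kdrl, and HSPC at 36 hpf little itga2b and a high mitochondrial share, so these directions are between labels.

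EC libraries were compared with DN libraries over the same 3 stages. The genes with the largest increase in libraries labelled EC were lysozyme lyz (6.07 ± 0.42), the neutrophil protease npsn (5.64 ± 0.60), the granule proteoglycan srgn (5.58 ± 0.32), the chemokine receptor ccr9a (5.57 ± 0.63) and myeloperoxidase mpx (5.25 ± 0.53). The largest decreases were in otpa (-5.06 ± 0.37), sncgb (-4.98 ± 0.43), mab21l2 (-4.85 ± 0.56), pcp4b (-4.83 ± 0.55) and calb2b (-4.71 ± 0.34). The largest adjusted p among these 10 was 1.4e-06. Of 26 endothelial genes, 9 were higher, 1 was lower and 16 did not pass (10 adjusted over the list alone, camera adjusted p = 2.2e-07, adjusted p = 0.261 with estimated correlation). Members included the ETS factors fli1a (4.16 ± 0.52), also in the HSPC regulator list, and fli1b (2.41 ± 0.56). Among 27 HSPC regulator genes 11 were higher, 3 were lower and 13 did not pass (15 adjusted over the list alone, camera adjusted p = 3.8e-06, adjusted p = 0.408 with estimated correlation). Examples were myb, needed for definitive HSPCs, at 3.87 ± 0.38 and the lymphoid factor ikzf1 at 2.68 ± 0.63. Of 14 thrombocyte genes, 5 were higher and 9 did not pass (5 adjusted over the list alone, camera adjusted p = 7.8e-05, adjusted p = 0.302 with estimated correlation). Members included fgl2a at 3.38 ± 0.33 and tubb1 at 2.43 ± 0.40. Among 32 neural genes 32 were lower (32 adjusted over the list alone, camera adjusted p = 2.6e-18, adjusted p = 0.194 with estimated correlation). Examples were snap25a at -4.53 ± 0.49 and elavl4 at -4.52 ± 0.42. Of 46 DNA replication (G1/S) genes, 26 were higher and 20 did not pass (29 adjusted over the list alone, camera adjusted p = 1.3e-19, adjusted p = 0.244 with estimated correlation). Members included the helicase subunits mcm4 (3.24 ± 0.34) and mcm2 (3.18 ± 0.33). Among 44 mitosis (G2/M) genes 16 were higher and 28 did not pass (17 adjusted over the list alone, camera adjusted p = 2.2e-15, adjusted p = 0.261 with estimated correlation). Examples were the condensins smc2 (2.80 ± 0.36) and ncapg (2.71 ± 0.32). Of 81 ribosomal list genes, 65 were higher, 1 was lower and 15 did not pass (68 adjusted over the list alone, camera adjusted p = 2.7e-33, adjusted p = 0.290 with estimated correlation). Members included rps9 at 1.95 ± 0.28 and rpl4 at 1.83 ± 0.24. Among 48 hox genes 48 were lower (48 adjusted over the list alone, camera adjusted p = 1.1e-21, adjusted p = 0.188 with estimated correlation). Examples were hoxc12a at -4.63 ± 0.51 and hoxa9b at -4.30 ± 0.38. In this comparison limma called 6416 of 21024 genes, 1219 higher and 5197 lower. At 36 hpf alone it called 446 higher and 254 lower, and at 4 dpf alone 656 higher and 7279 lower. The higher and lower counts were 2849 and 4666 without both low-complexity libraries, 1232 and 7828 without EC 4 dpf replicate 1, and 2748 and 4587 without EC 4 dpf replicate 2. The low kdrl of the libraries labelled EC at 3 and 4 dpf stands beside every direction here.

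HSPC libraries were compared with DN libraries over the same 3 stages, by their labels. Higher genes included stc1l (5.78 ± 1.29), the zinc finger gene blf (5.50 ± 0.90), ccr9a (4.98 ± 0.63), rgs13 (4.91 ± 0.96) and tagapb (4.45 ± 0.34, listed at 0 in both DN 36 hpf libraries). The largest decreases were in otpa (-6.64 ± 0.37), sncb (-6.19 ± 0.47), pcp4b (-6.10 ± 0.55), snap25b (-6.05 ± 0.40) and mab21l2 (-5.97 ± 0.56), of which otpa, pcp4b and snap25b were listed at 0 in both HSPC 3 dpf libraries. Of 27 HSPC regulator genes, 15 were higher, 3 were lower and 9 did not pass (20 adjusted over the list alone, camera adjusted p = 2.3e-06, adjusted p = 0.403 with estimated correlation). Members included myb at 4.17 ± 0.38, ikzf1 at 3.43 ± 0.63 and the homeobox gene meis1b at -3.01 ± 0.48. Among 14 thrombocyte genes 6 were higher and 8 did not pass (6 adjusted over the list alone, camera adjusted p = 1.5e-04, adjusted p = 0.326 with estimated correlation). Examples were the thrombopoietin receptor mpl at 2.33 ± 0.44, listed at 0 in DN at 3 and 4 dpf, and nfe2 at 1.85 ± 0.59. Of 26 endothelial genes, 2 were higher, 3 were lower and 21 did not pass (5 adjusted over the list alone, camera adjusted p = 0.173). Members included fli1a at 3.46 ± 0.52 and the VEGF receptor flt1 at -1.55 ± 0.22, listed at 0 in HSPC at 3 dpf. Among 32 neural genes 32 were lower (32 adjusted over the list alone, camera adjusted p = 3.6e-21, adjusted p = 0.186 with estimated correlation). Examples were elavl3 at -5.43 ± 0.42 and gng3 at -5.42 ± 0.41. Of 46 DNA replication (G1/S) genes, 32 were higher and 14 did not pass (37 adjusted over the list alone, camera adjusted p = 2.2e-18, adjusted p = 0.244 with estimated correlation). Members included mcm6 at 3.11 ± 0.74 and thymidylate synthase tyms at 2.92 ± 0.74. Among 44 mitosis (G2/M) genes 20 were higher and 24 did not pass (25 adjusted over the list alone, camera adjusted p = 5.5e-13, adjusted p = 0.302 with estimated correlation). Examples were cks2 at 2.56 ± 0.58 and cdk1 at 2.35 ± 0.71. Of 81 ribosomal list genes, 67 were higher, 1 was lower and 13 did not pass (68 adjusted over the list alone, camera adjusted p = 1.5e-29, adjusted p = 0.316 with estimated correlation). Members included rplp1 at 1.76 ± 0.26 and rpl3 at 1.70 ± 0.26. Among 48 hox genes 48 were lower (48 adjusted over the list alone, camera adjusted p = 1.7e-23, adjusted p = 0.183 with estimated correlation). An example was hoxc12a at -5.51 ± 0.51. The list member that moved against its ribosomal group, rps8b (-1.92 ± 0.30), has a close copy with which reads may be shared. Here 6437 of 21024 genes, 1457 higher and 4980 lower, were called by limma, with 588 higher and 942 lower at 36 hpf alone and 648 higher and 4543 lower at 4 dpf alone. Calls of higher and lower genes were 951 and 5277 with a pseudocount of 0.1 and 2464 and 5208 without both low-complexity libraries. Beside these directions, HSPC libraries at 36 hpf held itga2b at 0.428 and 0 FPKM, mitochondrial genes at 25.16% and 25.38% of FPKM and epidermal and muscle lists above DN.

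Within the HSPC sort, 3 dpf was compared with 36 hpf, where dissection may differ as well as stage. The chemokine receptor ccr9a went from 6.27 and 4.08 FPKM to 299 and 303 FPKM (5.63 ± 1.09), hdac7b from 0.701 and 0.204 FPKM to 83.2 and 62.9 FPKM (5.68 ± 1.27), and GZMM (4.84 ± 0.56), il2rga (4.81 ± 1.16) and tnfsf18 (4.68 ± 1.04) also rose, il2rga encoding the shared cytokine receptor chain. The largest falls were in lye, at 1171 and 1227 FPKM at 36 hpf, in s100a11, at 1116 and 1030 FPKM, in foxq1a, at 473 and 538 FPKM and in the troponin tnni2a.4, at 469 and 482 FPKM, all 4 being listed at 0 in both 3 dpf libraries. Another fall was in elovl7b (-9.09 ± 1.32). Of 27 HSPC regulator genes, 6 were higher, 2 were lower and 19 did not pass (13 adjusted over the list alone, camera adjusted p = 1.7e-05, adjusted p = 0.461 with estimated correlation). Members included lmo2 at 3.50 ± 1.13, myb at 3.47 ± 0.66 and meis1a at -3.38 ± 0.55. Among 14 thrombocyte genes 3 were higher and 11 did not pass (6 adjusted over the list alone, camera adjusted p = 9.4e-04, adjusted p = 0.398 with estimated correlation). Examples were mpl at 3.27 ± 0.75 and itga2b at 2.78 ± 0.69. Of 34 skeletal muscle genes, 30 were lower and 4 did not pass (31 adjusted over the list alone, camera adjusted p = 7.3e-21, adjusted p = 0.168 with estimated correlation). Members included mylpfa at -8.81 ± 1.29 and creatine kinase ckma at -8.03 ± 1.16. Among 34 epidermis genes 34 were lower (34 adjusted over the list alone, camera adjusted p = 7.3e-21, adjusted p = 0.191 with estimated correlation). An example was the claudin cldne at -7.53 ± 1.29. Of 32 neural genes, 31 were lower and 1 did not pass (31 adjusted over the list alone, camera adjusted p = 5.2e-16, adjusted p = 0.234 with estimated correlation). Members included sncb at -5.65 ± 0.81 and gap43 at -5.26 ± 0.86. Among 81 ribosomal list genes 27 were higher and 54 did not pass (53 adjusted over the list alone, camera adjusted p = 1.6e-21, adjusted p = 0.403 with estimated correlation). Examples were rpl6 at 1.52 ± 0.42 and rpl3 at 1.48 ± 0.45. Of 48 hox genes, 44 were lower and 4 did not pass (47 adjusted over the list alone, camera adjusted p = 1.0e-19, adjusted p = 0.191 with estimated correlation). Among them hoxb9a was at 43.8 and 54.6 FPKM and hoxb1b at 30.4 and 31.1 FPKM at 36 hpf, both listed at 0 in both 3 dpf libraries. These falls stand beside 13459 and 13274 genes above 0 at 3 dpf against 20520 and 19859 at 36 hpf. They also stand beside little itga2b and a higher mitochondrial share at 36 hpf. The test called 4653 of 21024 genes, 530 higher and 4123 lower. Higher and lower genes numbered 258 and 4495 with a pseudocount of 0.1, 314 and 5427 with median-of-ratios scaling, 2503 and 5800 with arrayWeights, 1820 and 4296 with only the groups compared, 260 and 5167 by limma-voom, 2445 and 5420 without both low-complexity libraries, and 279 and 2984 without HSPC 3 dpf replicate 1. The total was 3098 or 2939 without HSPC 36 hpf replicate 1 or 2 and 3094 without HSPC 3 dpf replicate 2.

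Libraries labelled HSPC were compared between 3 and 4 dpf. Red cell carbonic anhydrase cahz went from 3.39 and 1.61 FPKM to 120.2 and 554 FPKM (6.26 ± 0.68, adjusted p = 2.3e-04), alas2 from 2.04 and 0.0338 FPKM to 49.5 and 226 FPKM (5.92 ± 0.77, adjusted p = 0.00152), and the globins hbae1.3 (5.68 ± 0.81), hbbe2 (5.51 ± 0.57) and hbbe1.3 (5.47 ± 1.02) rose with them. The phosphatase gene DUSP26 fell (-3.14 ± 0.54, adjusted p = 0.0169). Among 9 embryonic and larval globin genes 5 were higher and 4 did not pass (6 adjusted over the list alone, camera adjusted p = 4.4e-16, adjusted p = 0.0359 with estimated correlation). An example was hbae3 at 5.31 ± 0.50. Of 24 erythroid genes, 2 were higher and 22 did not pass (7 adjusted over the list alone, camera adjusted p = 2.9e-08, adjusted p = 0.381 with estimated correlation). By limma 0 of 27 HSPC regulator genes passed (4 at an unadjusted p under 0.05, 0 by voom, 2 adjusted over the list alone, camera adjusted p = 5.4e-04, adjusted p = 0.598 with estimated correlation). An example was myb at -0.22 ± 0.66. Thrombocyte genes passed in 0 of 14 cases by limma (6 at an unadjusted p under 0.05, 1 by voom, 4 adjusted over the list alone, camera adjusted p = 0.865). An example was tubb1 at 1.90 ± 0.70. Its median was -0.01 and its mean 0.11 on the log2 scale. Among 34 skeletal muscle genes limma called 0 (13 at an unadjusted p under 0.05, 5 by voom, 0 adjusted over the list alone, camera adjusted p = 1.1e-08, adjusted p = 0.302 with estimated correlation). An example was actc1b at 2.95 ± 1.12. No call was made by limma among 34 epidermis genes (11 at an unadjusted p under 0.05, 3 by voom, 5 adjusted over the list alone, camera adjusted p = 1.1e-06, adjusted p = 0.477 with estimated correlation). An example was krt4 at 0.45 ± 0.91. Ribosomal list genes passed in 0 of 81 cases by limma (12 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 2.0e-17, adjusted p = 0.485 with estimated correlation). An example was rps15 at -1.07 ± 0.49. HSPC 4 dpf replicate 2, with mitochondrial genes at 43.85% of FPKM, held the epidermal list at 3.86 and the muscle list at 3.13, against 2.13 and 0.82 in replicate 1, and had itga2b listed at 0. Of 21024 genes 37 were called, 25 higher and 12 lower (19 and 5 with a common FPKM sum). An unadjusted p under 0.05 was found for 2105, and 0 were called on the groups compared alone. The higher and lower counts were 96 and 10 with a pseudocount of 0.1, 15 and 7 with median-of-ratios scaling, 15 and 3 with arrayWeights, 601 and 93 by limma-voom, 147 and 17 without both low-complexity libraries, 7 and 8 without HSPC 3 dpf replicate 1, and 11 and 34 without HSPC 3 dpf replicate 2. The total was 1709 or 9 without HSPC 4 dpf replicate 1 or 2.

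Kidney HSPC libraries at 3 mpf were compared with tail HSPC libraries at 4 dpf. The adult globin gene hbaa1 was at 2548 and 915 FPKM and hbaa2 at 456 and 135 FPKM in the kidney and both were listed at 0 at 4 dpf, and hbba2 rose (7.62 ± 0.74). Larval hbae3 (-10.80 ± 0.50), hbbe1.1 (-10.52 ± 0.58), hbbe2 (-8.52 ± 0.57) and hbae1.3 (-8.30 ± 0.81) fell, and hbbe1.3 was at 9.79 and 212 FPKM at 4 dpf and listed at 0 in the kidney. The germ cell genes ddx4 (8.31 ± 0.67) and piwil1 (7.69 ± 0.70) were higher in the kidney, ddx4 at 181 and 631 FPKM. Of 9 embryonic and larval globin genes, 5 were lower and 4 did not pass (6 adjusted over the list alone, camera adjusted p = 3.7e-20, adjusted p = 0.0223 with estimated correlation). Among 20 antigen presentation genes 12 were higher and 8 did not pass (14 adjusted over the list alone, camera adjusted p = 3.4e-09, adjusted p = 0.164 with estimated correlation). Examples were the invariant chains cd74a at 6.69 ± 0.78 and cd74b at 5.50 ± 0.99. Of 34 interferon and antiviral genes, 16 were higher and 18 did not pass (19 adjusted over the list alone, camera adjusted p = 4.0e-09, adjusted p = 0.199 with estimated correlation). Members included b2m at 6.16 ± 1.17 and isg15 at 3.81 ± 0.81. Among 24 erythroid genes 1 was lower and 23 did not pass (0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 in limma and 1 by voom, camera adjusted p = 2.7e-10, adjusted p = 0.302 with estimated correlation). This was slc4a1a, the red cell anion exchanger (-2.65 ± 0.75). Of 34 skeletal muscle genes, 1 was higher, 2 were lower and 31 did not pass (6 adjusted over the list alone, camera adjusted p = 1.1e-09, adjusted p = 0.277 with estimated correlation). Members included pvalb1 at -4.09 ± 1.23, actc1a at -2.61 ± 0.68 and acta1a at 1.81 ± 0.53. Among 27 HSPC regulator genes 1 was higher and 26 did not pass (0 adjusted over the list alone, with 7 at an unadjusted p under 0.05 in limma and 2 by voom, camera adjusted p = 0.138). This was mpl (2.35 ± 0.75). Its median was 0.43 and its mean 0.39 on the log2 scale. Of 14 thrombocyte genes, 4 were higher and 10 did not pass (4 adjusted over the list alone, camera adjusted p = 0.944). Members included itga2b at 3.38 ± 0.69 and P-selectin selp at 2.88 ± 0.45. Site, age and dissection differed together and cannot be separated, and HSPC 4 dpf replicate 2 had itga2b listed at 0. Genes above 0 were 22440 and 23100 in the kidney and 17866 and 11265 at 4 dpf. The median log2 fold change of all genes was 0.56. In all, limma called 2592 of 21024 genes, 2494 higher and 98 lower, with 5627 at an unadjusted p under 0.05. Fitted on these 2 groups alone it called 0. Calls of higher and lower genes were 2779 and 53 with a pseudocount of 0.1, 631 and 37 with arrayWeights, 3780 and 72 by limma-voom, 1270 and 187 without both low-complexity libraries, and 3306 and 54 without HSPC 3 mpf replicate 1. The total was 4564 or 785 without HSPC 4 dpf replicate 1 or 2 and 582 without HSPC 3 mpf replicate 2.

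Libraries labelled EC at 3 dpf were compared with those at 36 hpf, a comparison limited by their kdrl and itga2b levels and a possible difference of dissection. The vessel-secreted egfl7 fell from 20.3 and 14.8 FPKM to 0.285 and 0.722 FPKM (-3.62 ± 0.43), and the SOXF factor sox18 was at -3.84 ± 0.81. Rising genes were ccr9a (5.08 ± 1.09), hdac7b (5.01 ± 1.27), GZMM (4.81 ± 0.56) and the red cell factor gata1b (4.095 ± 0.88), while tnfrsf9b reached 9.31 and 21.5 FPKM from being listed at 0 in both 36 hpf libraries. The hatching enzyme genes he1a and he1b, near-identical copies, were at 1859 and 1361 FPKM and 682 and 416 FPKM at 36 hpf, he1a fell (-10.50 ± 0.48) and he1b was listed at 0 at 3 dpf, as was aqp8b, from 219 and 314 FPKM. The hatching gland protease ctslb (-7.73 ± 0.38) and hbbe3 (-9.76 ± 0.83) also fell. Among 26 endothelial genes 11 were lower and 15 did not pass (15 adjusted over the list alone, camera adjusted p = 5.0e-06, adjusted p = 0.312 with estimated correlation). Examples were cldn5b at -2.86 ± 0.56 and sox7 at -2.78 ± 0.77. Of 13 arterial genes, 7 were lower and 6 did not pass (9 adjusted over the list alone, camera adjusted p = 5.1e-06, adjusted p = 0.261 with estimated correlation). Members included the Notch genes notch3 (-4.44 ± 0.65) and dll4 (-2.68 ± 0.54). Among 18 venous, lymphatic and scavenger endothelial genes 8 were lower and 10 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.403 with estimated correlation). Examples were ephb4a at -2.83 ± 0.76 and the scavenger receptor stab2 at -2.51 ± 0.43. Of 34 skeletal muscle genes, 15 were lower and 19 did not pass (27 adjusted over the list alone, camera adjusted p = 3.6e-12, adjusted p = 0.244 with estimated correlation). Members included acta1a at -4.88 ± 0.53 and tnnt3a at -4.64 ± 0.78. Among 34 epidermis genes 26 were lower and 8 did not pass (31 adjusted over the list alone, camera adjusted p = 1.1e-15, adjusted p = 0.244 with estimated correlation). Examples were anxa1c at -5.63 ± 0.80 and krt4 at -5.03 ± 0.91. Of 32 neural genes, 20 were lower and 12 did not pass (25 adjusted over the list alone, camera adjusted p = 5.3e-13, adjusted p = 0.261 with estimated correlation). Members included sox2 at -5.73 ± 0.50 and gfap at -4.82 ± 0.57. Among 81 ribosomal list genes 2 were higher and 79 did not pass (0 adjusted over the list alone, with 35 at an unadjusted p under 0.05 in limma and 0 by voom, camera adjusted p = 1.0e-19, adjusted p = 0.441 with estimated correlation). These were rpl6 (1.37 ± 0.42) and rplp0 (1.17 ± 0.35). Of 48 hox genes, 25 were lower and 23 did not pass (31 adjusted over the list alone, camera adjusted p = 2.0e-12, adjusted p = 0.273 with estimated correlation). Members included hoxb6b at -4.17 ± 0.51 and hoxb5b at -3.59 ± 0.42. Beside each of these groups stand the kdrl and itga2b levels of both stages. The fit called 2635 of 21024 genes, 183 higher and 2452 lower. Higher and lower genes numbered 34 and 996 with a pseudocount of 0.1, 1922 and 4690 with arrayWeights, 1408 and 3873 with only the groups compared, 45 and 714 by limma-voom, and 1493 and 3650 without both low-complexity libraries. The total was 1289 or 1201 without EC 36 hpf replicate 1 or 2 and 1081 or 1512 without EC 3 dpf replicate 1 or 2.

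Libraries labelled EC at 4 dpf were compared with those at 3 dpf, and 4 genes were called, all lower. The urocortin gene ucn3l (-3.79 ± 0.51, adjusted p = 0.0121) met the naming rule, and the other 3 were named after their values were seen: si:dkey-18a10.3 (-4.26 ± 0.64, adjusted p = 0.0221), si:ch211-184m13.4 (-2.06 ± 0.33, adjusted p = 0.0335) and si:dkey-238m4.4 (-1.75 ± 0.24, adjusted p = 0.0121). Replicate 2 at 4 dpf had 2483 genes above 0, and the median log2 fold change of all genes was -0.85, so list values are read against that shift. Among 32 neural genes limma called 0 (26 at an unadjusted p under 0.05, 0 by voom, 26 adjusted over the list alone, camera adjusted p = 2.3e-11, adjusted p = 0.284 with estimated correlation). An example was vamp2 at -3.49 ± 0.73. No call was made by limma among 48 hox genes (28 at an unadjusted p under 0.05, 0 by voom, 24 adjusted over the list alone, camera adjusted p = 5.0e-06, adjusted p = 0.513 with estimated correlation). An example was hoxb9a at -2.70 ± 0.59. Embryonic and larval globin genes passed in 0 of 9 cases by limma (4 at an unadjusted p under 0.05, 0 by voom, 3 adjusted over the list alone, camera adjusted p = 2.4e-07, adjusted p = 0.183 with estimated correlation). Examples were hbbe1.1 at 2.08 ± 0.58 and hbbe3 at -1.61 ± 0.83. Among 44 mitosis (G2/M) genes limma called 0 (8 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 1.4e-04, adjusted p = 0.661 with estimated correlation). Members included tpx2 at 1.78 ± 0.62 and aurkb at -2.18 ± 1.24. The test placed the list above the other genes although its median was -1.26 and its mean -0.64 on the log2 scale. By limma 0 of 13 heme synthesis genes passed (4 at an unadjusted p under 0.05, 0 by voom, 3 adjusted over the list alone, camera adjusted p = 1.1e-04, adjusted p = 0.261 with estimated correlation). Examples were alas2 at 2.17 ± 0.77 and urod at -2.73 ± 1.64. The test placed the list above the other genes although its median was -0.33 and its mean -0.17 on the log2 scale. Endothelial genes passed in 0 of 26 cases by limma (7 at an unadjusted p under 0.05, 0 by voom, 3 adjusted over the list alone, camera adjusted p = 0.292). Members included fli1a at 0.76 ± 0.89 and tal1 at -3.22 ± 1.22. Its median was -0.55 and its mean -0.55 on the log2 scale. Among 13 arterial genes limma called 0 (4 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 0.901). An example was notch3 at -0.72 ± 0.65. No call was made by limma among 18 venous, lymphatic and scavenger endothelial genes (6 at an unadjusted p under 0.05, 0 by voom, 1 adjusted over the list alone, camera adjusted p = 0.799). Members included nr2f1a at -2.40 ± 0.64 and ctsla at 0.87 ± 0.61. Over all genes 6007 had an unadjusted p under 0.05 in limma. The higher and lower counts were 0 and 0 with a pseudocount of 0.1, 0 and 44 with no filter, 0 and 0 with arrayWeights, 0 and 0 with only the groups compared, 0 and 0 by limma-voom, 4 and 19 without both low-complexity libraries, and 1 and 0 without EC 4 dpf replicate 2. The total was 1 or 15 without EC 3 dpf replicate 1 or 2 and 10582 without EC 4 dpf replicate 1. The count without replicate 1 of EC 4 dpf rests on the low-complexity replicate alone, which is then assumed to vary like the other groups.

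From 36 to 52 hpf, hbbe2 rose in the double-negative sort by 5.57 ± 0.57, alas2 by 4.86 ± 0.77 and rfesd by 5.20 ± 0.67, with the cartilage gene matn3a at 5.16 ± 0.97 and tgm2l at 5.15 ± 0.73. The neuronal factor phox2bb fell from 33.2 and 41.0 FPKM to 0.132 and 0.0488 FPKM (-5.12 ± 0.43), and hoxb5b (-4.74 ± 0.42), hoxc5a (-4.60 ± 0.49), pyya (-4.32 ± 0.54) and hoxc1a (-3.72 ± 0.35) fell as well. The largest adjusted p among these 10 was 0.00971. Among 9 embryonic and larval globin genes 4 were higher and 5 did not pass (9 adjusted over the list alone, camera adjusted p = 5.4e-18, adjusted p = 0.0269 with estimated correlation). An example was hbae3 at 4.36 ± 0.50. Of 24 erythroid genes, 6 were higher and 18 did not pass (16 adjusted over the list alone, camera adjusted p = 7.3e-21, adjusted p = 0.187 with estimated correlation). Members included cahz at 4.81 ± 0.68 and slc4a1a at 4.04 ± 0.75. Among 17 neutrophil genes 2 were higher and 15 did not pass (8 adjusted over the list alone, camera adjusted p = 8.5e-13, adjusted p = 0.164 with estimated correlation). These were srgn (4.32 ± 0.55) and lyz (4.27 ± 0.72). Of 18 notochord and cartilage genes, 9 were higher and 9 did not pass (11 adjusted over the list alone, camera adjusted p = 1.3e-16, adjusted p = 0.149 with estimated correlation). Members included epyc at 4.42 ± 0.59 and the brachyury gene ta at 4.40 ± 0.60. Among 37 fibroblast and mesenchyme genes 5 were higher and 32 did not pass (19 adjusted over the list alone, camera adjusted p = 4.6e-21, adjusted p = 0.164 with estimated correlation). Examples were fmoda at 2.81 ± 0.44 and prrx1a at 2.65 ± 0.53. Of 46 niche ligand and adhesion genes, 3 were higher and 43 did not pass (14 adjusted over the list alone, camera adjusted p = 2.0e-05, adjusted p = 0.403 with estimated correlation). Members included the granulocyte factor csf3b at 4.22 ± 0.97, wnt5a at 2.04 ± 0.51 and ccl25b at 1.48 ± 0.32. In this step 411 of 21024 genes, 215 higher and 196 lower, were called, against 201 higher and 390 lower with a common FPKM sum. Calls of higher and lower genes were 28 and 15 with a pseudocount of 0.1, 226 and 362 with no filter, 334 and 280 with median-of-ratios scaling, 1787 and 2593 with arrayWeights, 1280 and 2194 with only the groups compared, 44 and 17 by limma-voom, 1002 and 1198 without both low-complexity libraries, 39 and 42 without DN 36 hpf replicate 1, and 34 and 35 without DN 36 hpf replicate 2. The total was 68 or 57 without DN 52 hpf replicate 1 or 2.

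In the double-negative sort between 52 hpf and 3 dpf, neurod6b rose from 0.238 and 0.146 FPKM to 89.96 and 97.6 FPKM (6.31 ± 0.49), with the myelin genes mag (5.71 ± 0.48) and mbpa (4.84 ± 0.50), the bile acid binding gene fabp6 (4.94 ± 0.88) and crp1 (4.79 ± 0.34). The globins hbbe3 (-9.19 ± 0.83) and hbbe1.3 (-5.62 ± 1.02), urod, a heme synthesis enzyme (-5.29 ± 1.64), slc4a1a (-5.24 ± 0.75) and col2a1a (-5.17 ± 1.02) fell. Among 24 erythroid genes 9 were lower and 15 did not pass (17 adjusted over the list alone, camera adjusted p = 2.2e-13, adjusted p = 0.254 with estimated correlation). Examples were rhag at -4.92 ± 1.40 and alas2 at -4.90 ± 0.77. Of 37 fibroblast and mesenchyme genes, 1 was higher, 19 were lower and 17 did not pass (28 adjusted over the list alone, camera adjusted p = 1.4e-16, adjusted p = 0.183 with estimated correlation). Members included fn1b at -4.36 ± 0.65 and col1a2 at -3.55 ± 0.96. Among 18 notochord and cartilage genes 12 were lower and 6 did not pass (12 adjusted over the list alone, camera adjusted p = 2.3e-11, adjusted p = 0.183 with estimated correlation). Examples were col9a3 at -4.94 ± 0.97 and ta at -4.93 ± 0.60. Of 43 matrix receptor and remodelling genes, 18 were lower and 25 did not pass (22 adjusted over the list alone, camera adjusted p = 4.0e-14, adjusted p = 0.191 with estimated correlation). Members included mmp9 at -4.60 ± 0.79 and timp2b at -4.30 ± 0.97. Among 46 niche ligand and adhesion genes 2 were higher, 15 were lower and 29 did not pass (25 adjusted over the list alone, camera adjusted p = 7.5e-11, adjusted p = 0.244 with estimated correlation). Examples were csf3b at -5.03 ± 0.97, il34 at -3.67 ± 0.75 and cxcl12a, a ligand that retains HSPCs, at 3.13 ± 0.53. Of 81 ribosomal list genes, 1 was higher, 6 were lower and 74 did not pass (3 adjusted over the list alone, camera adjusted p = 4.1e-16, adjusted p = 0.513 with estimated correlation). Members included rpl5a at -1.83 ± 0.39 and rps8b, which has a close copy, at 2.42 ± 0.52. The call covered 2848 of 21024 genes, 2025 higher and 823 lower (2702 and 621 with a common FPKM sum). DN 3 dpf correlated more with 36 than with 52 hpf, so more than stage may differ here. Higher and lower genes numbered 100 and 70 with a pseudocount of 0.1, 4640 and 2855 with arrayWeights, 4194 and 2101 with only the groups compared, 26 and 49 by limma-voom, and 3773 and 2244 without both low-complexity libraries. The total was 1266 or 1375 without DN 52 hpf replicate 1 or 2 and 1449 or 1489 without DN 3 dpf replicate 1 or 2.

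Between 3 and 4 dpf few double-negative genes passed the test. Tyrosine aminotransferase tat rose from 3.64 and 1.41 FPKM to 68.3 and 58.0 FPKM (4.26 ± 0.67), with the peptide genes galn (3.57 ± 0.64) and insl5b (3.14 ± 0.47), hapln2 (3.10 ± 0.56) and cathepsin ctsbb (2.92 ± 0.54). Those that fell were g0s2 (-2.53 ± 0.50), trhra (-2.04 ± 0.38), drgx (-1.81 ± 0.35), samd12 (-1.70 ± 0.34) and ush1gb (-1.61 ± 0.32), with adjusted p up to 0.0482. Among 46 niche ligand and adhesion genes 1 was higher and 45 did not pass (1 adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.625 with estimated correlation). This was the thymus and gut chemokine ccl25b (2.23 ± 0.32). Among 40 dissociation and immediate early stress genes limma called 0 (13 at an unadjusted p under 0.05, 0 by voom, 2 adjusted over the list alone, camera adjusted p = 4.3e-15, adjusted p = 0.0223 with estimated correlation). An example was junbb at 1.21 ± 0.31. By limma 0 of 81 ribosomal list genes passed (10 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 7.0e-19, adjusted p = 0.459 with estimated correlation). An example was rps15 at 0.75 ± 0.49. Skeletal muscle genes passed in 0 of 34 cases by limma (19 at an unadjusted p under 0.05, 0 by voom, 8 adjusted over the list alone, camera adjusted p = 3.9e-18, adjusted p = 0.183 with estimated correlation). An example was actc1b at 2.59 ± 1.12. Among 34 epidermis genes limma called 0 (3 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 2.8e-07, adjusted p = 0.446 with estimated correlation). An example was krt4 at 0.99 ± 0.91. No call was made by limma among 37 fibroblast and mesenchyme genes (6 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.370 with estimated correlation). An example was col1a1a at 1.54 ± 1.08. The test over all groups called 42 of 21024 genes, 29 higher and 13 lower (27 and 29 with a common FPKM sum). Median-of-ratios scaling gave 36 and 40. In limma 1314 had an unadjusted p under 0.05, and 0 were called on the 2 groups alone. The higher and lower counts were 1 and 0 with a pseudocount of 0.1, 44 and 35 with no filter, 567 and 265 with arrayWeights, 0 and 0 by limma-voom, and 256 and 47 without both low-complexity libraries. The total was 24 or 6 without DN 3 dpf replicate 1 or 2 and 22 or 18 without DN 4 dpf replicate 1 or 2. None of the 10 genes named first was called with a pseudocount of 0.1.

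Within the kidney at 3 mpf, HSPC libraries were compared with DN libraries. CD41 itself was higher, itga2b at 14.9 and 39.7 FPKM against 0.583 and 2.46 FPKM (3.45 ± 0.69), with mpl at 3.24 ± 0.75. The largest increases were in cdk21 (4.23 ± 0.52), the germ cell genes tdrd5 (4.00 ± 0.73) and tdrd9 (3.72 ± 0.62), tsn (3.72 ± 0.89) and ccdc106b (3.71 ± 0.40). The largest decreases were in saxo2, a gene of cilia and flagella, at 2.15 and 3.63 FPKM against 278 and 230.3 FPKM (-6.06 ± 0.48), the cilium genes tekt1 at -5.50 ± 0.37 and rsph9 at -5.26 ± 0.44, with pvalb6 (-5.72 ± 0.60) and pimr72 (-5.34 ± 0.24), of a family with similar copies. Among 17 lymphoid genes 9 were lower and 8 did not pass (11 adjusted over the list alone, camera adjusted p = 2.7e-11, adjusted p = 0.164 with estimated correlation). Examples were the antibody light chain igic1s1 at -4.86 ± 0.51, cd79a at -3.89 ± 0.51 and rag2 at -3.37 ± 0.62. Of 14 thrombocyte genes, 5 were higher and 9 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00814, adjusted p = 0.538 with estimated correlation). Members included fgl2a at 3.34 ± 0.58 and itgb3b at 2.45 ± 0.59. Among 27 HSPC regulator genes 2 were higher and 25 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0561). These were fli1a (3.51 ± 0.89) and mpl. Of 24 erythroid genes, 1 was lower and 23 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.784 with estimated correlation). This was cahz (-2.98 ± 0.68). Among 17 neutrophil genes 1 was higher and 16 did not pass (1 adjusted over the list alone, camera adjusted p = 0.00885, adjusted p = 0.548 with estimated correlation). This was mmp9 (2.74 ± 0.79). No call was made by limma among 52 chromatin remodelling genes (9 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.833 with estimated correlation). An example was hdac1 at 1.66 ± 1.301. The fit over all groups called 1597 of 21024 genes, 504 higher and 1093 lower (358 and 1533 with median-of-ratios scaling). An unadjusted p under 0.05 was found for 4042, and limma called 0 on the 2 groups alone. Calls of higher and lower genes were 334 and 532 with a pseudocount of 0.1, 76 and 557 with arrayWeights, 362 and 319 by limma-voom, 2817 and 1666 without both low-complexity libraries, 838 and 746 without HSPC 3 mpf replicate 1, 109 and 1049 without HSPC 3 mpf replicate 2, 315 and 1961 without DN 3 mpf replicate 1, and 1071 and 931 without DN 3 mpf replicate 2.

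The change from 36 hpf to 3 dpf was compared between HSPC and EC libraries, as a difference. The larger falls in HSPC libraries were in foxq1a (-6.90 ± 1.26), apoa1a (-6.56 ± 1.24), apoa1b (-6.25 ± 0.92), apoa2 (-5.57 ± 1.06) and s100a11 (-5.43 ± 1.03), of which all but apoa2 were listed at 0 in both HSPC 3 dpf libraries, so their size depends on the pseudocount. The hatching gland gene ctslb fell more in libraries labelled EC (6.05 ± 0.53), as did the copies he1a and he1b, which were at 24.4 and 27.8 FPKM (HSPC) and 1859 and 1361 FPKM (EC) and 7.22 and 14.4 FPKM (HSPC) and 682 and 416 FPKM (EC) at 36 hpf. The glucagon gene gcgb (2.99 ± 0.55) and tmprss9 (2.67 ± 0.52), both listed at 0 in the HSPC 3 dpf libraries, completed the named set. Among 26 endothelial genes 1 was higher and 25 did not pass (2 adjusted over the list alone, camera adjusted p = 2.0e-11, adjusted p = 0.191 with estimated correlation). This was VE-cadherin cdh5 (2.04 ± 0.41), listed at 0 in both HSPC 3 dpf libraries. Among 34 skeletal muscle genes limma called 0 (20 at an unadjusted p under 0.05, 5 by voom, 18 adjusted over the list alone, camera adjusted p = 3.6e-16, adjusted p = 0.191 with estimated correlation). An example was actc1b at -4.82 ± 1.59. By limma 0 of 34 epidermis genes passed (13 at an unadjusted p under 0.05, 2 by voom, 0 adjusted over the list alone, camera adjusted p = 1.9e-11, adjusted p = 0.302 with estimated correlation). An example was krt4 at -1.78 ± 1.28. Hox genes passed in 0 of 48 cases by limma (16 at an unadjusted p under 0.05, 9 by voom, 3 adjusted over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.385 with estimated correlation). An example was hoxd3a at -2.78 ± 0.93. Among 46 DNA replication (G1/S) genes limma called 0 (1 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 1.3e-05, adjusted p = 0.615 with estimated correlation). An example was pcna at 1.24 ± 0.89. No call was made by limma among 27 HSPC regulator genes (0 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.754 with estimated correlation). Members included myb at -0.03 ± 0.93 and tal1 at 0.57 ± 1.73. Thrombocyte genes passed in 0 of 14 cases by limma (1 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 0.581). An example was tubb1 at 1.298 ± 0.99. The difference was called for 59 of 21024 genes, 22 higher and 37 lower (25 and 75 with median-of-ratios scaling). In limma-voom tmprss9 was at -1.78 and cdh5 at -0.16, opposite in sign. Higher and lower genes numbered 2 and 2 with a pseudocount of 0.1, 42 and 96 with no filter, 224 and 949 with arrayWeights, 147 and 517 with only the groups compared, 6 and 306 by limma-voom, 82 and 418 without both low-complexity libraries, 15 and 10 without EC 36 hpf replicate 1, 17 and 16 without EC 36 hpf replicate 2, 18 and 16 without HSPC 36 hpf replicate 1, 15 and 14 without EC 3 dpf replicate 1, 19 and 17 without HSPC 3 dpf replicate 1, and 22 and 14 without HSPC 3 dpf replicate 2. The total was 31 without HSPC 36 hpf replicate 2 and 36 without EC 3 dpf replicate 2. HSPC libraries at 36 hpf held little itga2b and a high mitochondrial share, and EC libraries at 3 dpf little kdrl.

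The same change was compared between EC and DN libraries. Genes with a higher change in libraries labelled EC were GZMM (4.89 ± 0.79), myb (4.18 ± 0.93), spx (3.55 ± 0.96), ribonucleotide reductase rrm1 (3.47 ± 0.74) and ahcy (3.33 ± 0.71). Genes with a lower change were he1a (-8.43 ± 0.68), he1b (-7.73 ± 0.65), ctslb (-6.93 ± 0.53), tagln (-6.72 ± 0.89) and slc2a1a (-6.39 ± 0.60), of which he1b was listed at 0 in both groups at 3 dpf and ctslb in DN at 3 dpf. Of 26 endothelial genes, 3 were lower and 23 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.716 with estimated correlation). Members included egfl7 at -3.53 ± 0.61 and flt1 at -2.69 ± 0.55. Among 27 HSPC regulator genes 1 was higher and 26 did not pass (1 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.477 with estimated correlation). This was myb. Thrombocyte genes passed in 0 of 14 cases by limma (3 at an unadjusted p under 0.05, 0 by voom, 0 adjusted over the list alone, camera adjusted p = 8.4e-04, adjusted p = 0.394 with estimated correlation). Members included tubb1 at 1.43 ± 0.99 and f13a1b at -0.13 ± 1.49. Among 32 neural genes 5 were lower and 27 did not pass (26 adjusted over the list alone, camera adjusted p = 2.6e-11, adjusted p = 0.284 with estimated correlation). Examples were neurod1 at -4.84 ± 0.80 and isl1 at -3.54 ± 0.81. Of 46 DNA replication (G1/S) genes, 1 was higher and 45 did not pass (6 adjusted over the list alone, camera adjusted p = 1.9e-15, adjusted p = 0.269 with estimated correlation). This was rrm1. Among 44 mitosis (G2/M) genes 2 were higher and 42 did not pass (5 adjusted over the list alone, camera adjusted p = 1.2e-16, adjusted p = 0.261 with estimated correlation). These were ncapg (3.28 ± 0.79) and mki67 (3.10 ± 0.84). Of 81 ribosomal list genes, 7 were higher, 1 was lower and 73 did not pass (61 adjusted over the list alone, camera adjusted p = 2.2e-42, adjusted p = 0.245 with estimated correlation). Members included rpl3 at 2.39 ± 0.64 and rpl4 at 2.27 ± 0.58. Among 48 hox genes 10 were lower and 38 did not pass (33 adjusted over the list alone, camera adjusted p = 2.6e-15, adjusted p = 0.244 with estimated correlation). Examples were hoxb13a at -5.37 ± 1.202 and hoxc13b at -4.81 ± 0.80. In total 753 of 21024 genes, 30 higher and 723 lower, were called. The higher and lower counts were 3 and 30 with a pseudocount of 0.1, 83 and 1127 with no filter, 30 and 1150 with a common FPKM sum, 29 and 2116 with median-of-ratios scaling, 1911 and 5371 with arrayWeights, 1525 and 4605 with only the groups compared, 1 and 11 by limma-voom, and 949 and 2445 without both low-complexity libraries. The total was 179 or 136 without EC 36 hpf replicate 1 or 2, 118 or 173 without DN 36 hpf replicate 1 or 2, 75 or 364 without EC 3 dpf replicate 1 or 2, and 142 or 301 without DN 3 dpf replicate 1 or 2. The itga2b and kdrl levels of the libraries labelled EC at 3 dpf stand beside these directions too.

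**Figure D4:**
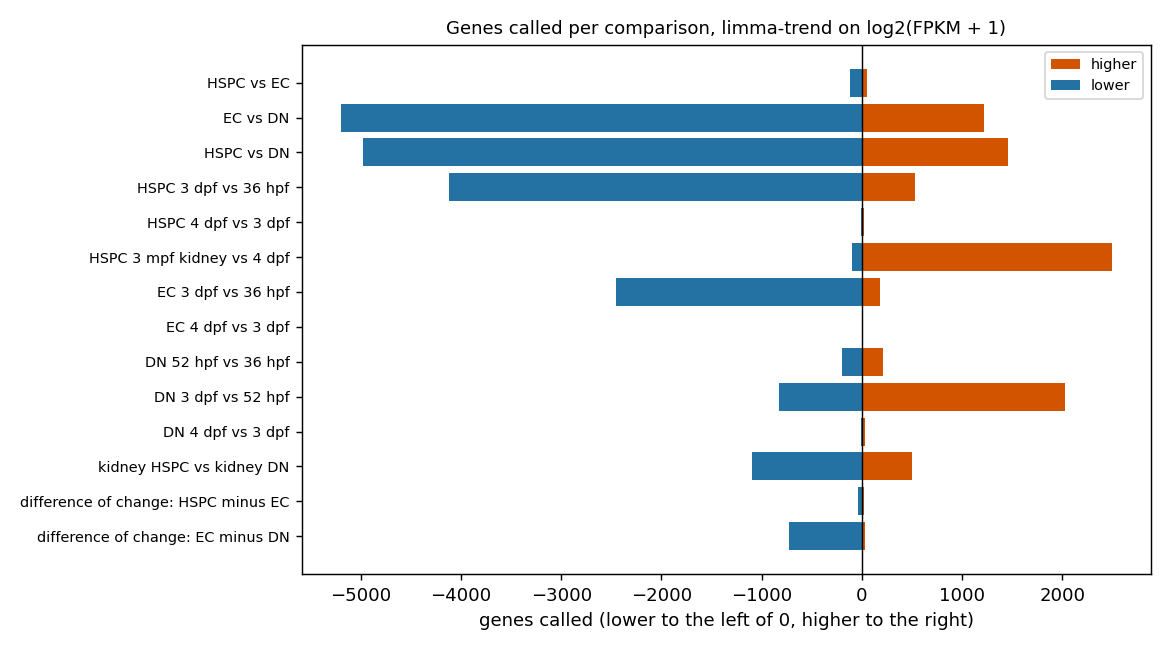
Genes called in each of the 14 comparisons by limma-trend on log2(FPKM + 1), lower to the left of 0 and higher to the right. HSPC against DN had 6437 and libraries labelled EC at 4 against 3 dpf had 4.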

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

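The tests of exchanged labels, of blood cells in the EC 3 dpf sort, of admixture of DN cells and of a lower share of sorted cells were chosen after the result was seen. The change from 36 hpf to 3 dpf differed between HSPC and EC libraries in 59 genes and between EC and DN libraries in 753, by the limma test of the difference itself. For HSPC minus EC the log2 differences were ctslb 6.05, he1a 5.74, he1b 5.57, gcgb 2.99, tmprss9 2.67, foxq1a -6.90, apoa1a -6.56, apoa1b -6.25, apoa2 -5.57 and s100a11 -5.43. List medians were endothelial 1.11, HSPC regulators 0.44, skeletal muscle -2.60, epidermis -2.10, DNA replication (G1/S) 0.99 and hox genes -1.14. For EC minus DN the log2 differences were GZMM 4.89, myb 4.18, spx 3.55, rrm1 3.47, ahcy 3.33, he1a -8.43, he1b -7.73, ctslb -6.93, tagln -6.72 and slc2a1a -6.39. Those list medians were endothelial -1.01, HSPC regulators 1.39, thrombocyte 0.64, neural -2.54, DNA replication (G1/S) 1.68, mitosis (G2/M) 1.99, ribosomal proteins 1.97 and hox genes -2.77.

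Libraries labelled EC at 3 dpf held little kdrl and high blood cell transcripts, which bears on both differences. An exchange of EC and HSPC labels is argued against: the highest HSPC minus the lowest EC 3 dpf endothelial list mean (log2) was -0.42, where an exchange needs HSPC above EC. Too few reads are argued against, as the shallower EC 3 dpf library would hold 221 kdrl reads at the lowest EC 36 hpf level. Blood cells in the sort cannot be told apart from other causes: 5 of 5 blood lists lay higher in both EC than in both DN libraries at 3 dpf, but that is the pattern itself and not a test. A loss of kdrl alone is argued against, as the endothelial list fell from 3.26 and 2.82 at 36 hpf to 1.67 and 1.68. A wider loss with stage stays open and was not tested.

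Few genes were called between EC 4 and 3 dpf, where replicate 2 at 4 dpf had 2483 genes above 0. Its read depth is argued against as the cause of that number, since replicate 1 thinned to the same reads had 16321. Whether replicate 2 alone set the result cannot be told apart from other causes: 1 gene was called without it and 23 without both low-complexity libraries, from 1 library at 4 dpf. The median log2 fold change of all genes, -0.12 without it and -0.85 with it, does not bear on the number called. A biological change from 3 to 4 dpf stays open.

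Epidermal and muscle transcripts were high in HSPC libraries at 36 hpf. Admixture of the DN population is argued against, as the lowest HSPC library lay above the highest DN library by 0.74 (muscle) and 1.01 (epidermis) on the log2 scale. A lower share of sorted cells that raised every other tissue alike is argued against by the neural list, at -0.67 for the highest HSPC minus the lowest EC library. Epidermal and muscle cells or their RNA entering the sort and expression in the sorted cells both stay open.

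Within-stage splits into other groups of the same sizes tested if chance can be excluded. For HSPC against EC it cannot: 31 of 100 splits gave as many genes as the real 167, the highest other 1918. Of 30 splits with both low-complexity 4 dpf libraries together, 29 gave as many, which points to a structure of the samples. For EC against DN (real 6416, highest other 5485) and HSPC against DN (6437, 5361) only the real split of 100 did. Most splits divide replicates that may be technical, so chance stays open.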

How the results depend on the processing

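Settings chosen after seeing the data are named above. Counts within 1.5 times of the value reported are left out here, except for the replicate block and in ranges over left-out replicates. For the other counts the cause was not tested. A fit of only the groups compared has fewer samples and also takes its spread from those groups alone, and its counts moved both down and up. HSPC minus EC and EC minus DN are the differences of change. With a pseudocount of 0.1 the counts were 67 (HSPC against EC), 106 (HSPC 4 against 3 dpf), 1030 (EC 3 dpf against 36 hpf), 0 (EC 4 against 3 dpf), 43 (DN 52 against 36 hpf), 170 (DN 3 dpf against 52 hpf), 1 (DN 4 against 3 dpf), 866 (kidney HSPC against DN), 4 (HSPC minus EC) and 33 (EC minus DN). With no filter they were 44 (EC 4 against 3 dpf), 79 (DN 4 against 3 dpf), 138 (HSPC minus EC) and 1210 (EC minus DN). A common FPKM sum gave 24 (HSPC 4 against 3 dpf) and 1180 (EC minus DN). Median-of-ratios scaling gave 22 (HSPC 4 against 3 dpf), 76 (DN 4 against 3 dpf), 100 (HSPC minus EC) and 2145 (EC minus DN). With arrayWeights there were 5 (HSPC against EC), 8303 (HSPC 3 dpf against 36 hpf), 18 (HSPC 4 against 3 dpf), 668 (kidney HSPC against 4 dpf), 6612 (EC 3 dpf against 36 hpf), 0 (EC 4 against 3 dpf), 4380 (DN 52 against 36 hpf), 7495 (DN 3 dpf against 52 hpf), 832 (DN 4 against 3 dpf), 633 (kidney HSPC against DN), 1173 (HSPC minus EC) and 7282 (EC minus DN). Fits of only the groups compared gave 66 (HSPC against EC), 0 (HSPC 4 against 3 dpf), 0 (kidney HSPC against 4 dpf), 5281 (EC 3 dpf against 36 hpf), 0 (EC 4 against 3 dpf), 3474 (DN 52 against 36 hpf), 6295 (DN 3 dpf against 52 hpf), 0 (DN 4 against 3 dpf), 0 (kidney HSPC against DN), 664 (HSPC minus EC) and 6130 (EC minus DN). By limma-voom on recovered reads there were 872 (HSPC against EC), 694 (HSPC 4 against 3 dpf), 759 (EC 3 dpf against 36 hpf), 0 (EC 4 against 3 dpf), 61 (DN 52 against 36 hpf), 75 (DN 3 dpf against 52 hpf), 0 (DN 4 against 3 dpf), 681 (kidney HSPC against DN), 312 (HSPC minus EC) and 12 (EC minus DN). Without both low-complexity 4 dpf libraries there were 630 (HSPC against EC), 7865 (HSPC 3 dpf against 36 hpf), 164 (HSPC 4 against 3 dpf), 1457 (kidney HSPC against 4 dpf), 5143 (EC 3 dpf against 36 hpf), 23 (EC 4 against 3 dpf), 2200 (DN 52 against 36 hpf), 6017 (DN 3 dpf against 52 hpf), 303 (DN 4 against 3 dpf), 4483 (kidney HSPC against DN), 500 (HSPC minus EC) and 3394 (EC minus DN). At 36 hpf alone there were 286 (HSPC against EC), 700 (EC against DN) and 1530 (HSPC against DN). At 4 dpf alone there were 16 (HSPC against EC). With an estimated correlation 5 lists were called, and in the other settings between 252 and 311. Leaving out each replicate gave 71 to 4752 (HSPC against EC), 5738 to 9060 (EC against DN), 1081 to 1512 (EC 3 dpf against 36 hpf), 25 to 36 (HSPC minus EC), 75 to 364 (EC minus DN), 5763 to 6521 (HSPC against DN), 2939 to 3263 (HSPC 3 dpf against 36 hpf), 57 to 81 (DN 52 against 36 hpf), 1266 to 1489 (DN 3 dpf against 52 hpf), 1 to 10582 (EC 4 against 3 dpf), 9 to 1709 (HSPC 4 against 3 dpf), 6 to 24 (DN 4 against 3 dpf), 582 to 4564 (kidney HSPC against 4 dpf) and 1158 to 2276 (kidney HSPC against DN), where a lone library is assumed to vary like the other groups. Of named genes and lists, 2 reversed, both by limma-voom in the difference HSPC minus EC: tmprss9 (-1.78) and cdh5 (-0.16). Named gene results no longer called were 120 with the other pseudocount, 102 by limma-voom, 77 in fits of only the groups compared, 36 with arrayWeights, 22 with no filter, 18 with median-of-ratios scaling, 9 with the replicate block, 7 without both low-complexity libraries and 5 with a common FPKM sum. Over all left-out replicates these were 503. A common FPKM sum shifted the median log2 fold change of all genes by -0.16 (EC against DN), -0.21 (HSPC against DN), -0.15 (DN 52 against 36 hpf), 0.23 (DN 3 dpf against 52 hpf), -0.11 (DN 4 against 3 dpf) and -0.15 (EC minus DN), and median-of-ratios scaling by -0.25 (EC against DN), -0.14 (HSPC against DN), -0.28 (HSPC 3 dpf against 36 hpf), -0.19 (EC 3 dpf against 36 hpf), 0.11 (EC 4 against 3 dpf), -0.30 (kidney HSPC against DN), -0.12 (HSPC minus EC) and -0.28 (EC minus DN), so changes near these sizes depend on the scaling. With the replicate number as a block no total moved by more than 1.5 times, among them 158 (HSPC against EC), 6391 (EC against DN), 6416 (HSPC against DN), 56 (HSPC minus EC) and 729 (EC minus DN), and 268 lists were called. In EC minus DN the block gave 48 higher genes, against 30. Same-numbered deviations correlated at -0.338 to 0.268 over 66 pairs of groups, 6 above 0.1. These pool stages, so pairing within a stage stays open.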

Other observations

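In libraries labelled EC against DN, 12 were higher and 1 lower of 25 genes (13 adjusted over the list alone, camera adjusted p = 4.7e-10, adjusted p = 0.164 with an estimated correlation) in the macrophage list. In the neutrophil list 14 were higher and 1 lower of 17 genes (15 adjusted over the list alone, camera adjusted p = 2.9e-12, adjusted p = 0.164 with an estimated correlation). Of the Notch signalling list, 0 were higher and 15 lower of 29 genes (17 adjusted over the list alone, camera adjusted p = 1.7e-08, adjusted p = 0.261 with an estimated correlation) in the same libraries at 3 dpf against 36 hpf.

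Kidney libraries held germ cell transcripts, singled out after their values were seen. ddx4, a germ cell helicase, was at 181 and 631 FPKM in HSPC and 19.2 and 98.96 FPKM in DN libraries, and dazl at 24.9 and 112 FPKM and 12.3 and 42.1 FPKM. The meiotic gene sycp3 was at 6.33 and 16.1 FPKM in HSPC and 57.6 and 121 FPKM in DN libraries. Their source was not tested.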
